A study of Mus musculus with 4 samples.

How the data were processed

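The samples were 4 RNA-seq libraries of back skin epidermis from C57BL/6 mice at postnatal day 63, 2 from wild type and 2 from LDB2-/- animals. Per the labels' protocols, skin was treated with dispase, an enzyme that loosens epidermis from dermis, RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA kit. Neither the kit's strandedness nor whether counting used strand is stated, so antisense and overlapping genes cannot be separated. The submitters' processing notes name bcl2fastq 1.8.4, HISAT2 2.1.0, an aligner, StringTie 1.3.4d, a transcript quantifier, and the genome build mm10. The settings of these tools are not given there.

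The deposited table held 17721 genes with Entrez gene IDs, and no gene symbol occurred more than once. The authors deposited read counts per gene, whole numbers that were not normalized, per the file headers. The authors also deposited FPKM, fragments per kilobase of transcript scaled to the size of the library, per the file headers, with column sums that differ between libraries. A further set of deposited columns held log2 values that the authors normalized between libraries, per the file headers, which do not name the method. The deposited table also held the authors' own comparison, a signed fold change treated here as a score, since it is negative where LDB2-/- is lower, and a Benjamini-Hochberg adjusted p-value per gene. The mean scaled count of that comparison was recomputed from the counts with DESeq2's median-of-ratios factors and differed by at most 0.000223%. All deposited genes had a count in at least 1 library.

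The test planned before the data were examined assumed that FPKM was the only unit and used limma on log2(FPKM + 1). The table held counts, so edgeR's quasi-likelihood test on the counts became the main test and the planned fit is given as an alternative. Genes with an FPKM of 1 or more in at least 2 libraries were tested, 12400 in all. Counts were scaled with TMM, whose factors were 1.105 and 1.128 in wild type and 0.920 and 0.872 in LDB2-/- libraries 1 and 2. The test was two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. The standard error of a log2 fold change is the one implied by the quasi-likelihood F statistic. The biological coefficient of variation was 0.194. A size rule without a test counted genes whose mean log2(FPKM + 1) differed by at least 1 with no overlap of the genotypes. On that scale the pseudocount of 1 understates the change of genes with low values. Fold changes against a genotype at 0 in both libraries are given as bounds against 3 counts over the group.

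The 36 gene lists of skin cell types and programmes were fixed before the data were examined, and 32 had the 5 tested members a list test needed. Lists were tested with limma's camera on log2(FPKM + 1) with a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry as alternatives. The rule for named genes was also fixed then: Ldb2, Ldb1, Lhx2 and the sex check genes, the 12 higher and 12 lower genes with the smallest p among those with an absolute log2 fold change of 1 or more and no overlap of the genotypes, leaving out unnamed models and small RNAs, and up to 4 tested members of each list with the largest absolute log2 fold change. In all, 6 unnamed models were passed over, and some genes that the rule selects are not reported here. Other list members named because they did not follow their list were chosen after their values were seen. So were the genes with the most counts in a library, and Ttn, Adipoq, Plin1 and Cfd.

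Alternatives were other pseudocounts, expression filters and scalings, fits with robust or untrended variance, the replicate number as a block, each library left out in turn, and, beyond the planned limma fit on FPKM, added after seeing the data, limma on the authors' normalized values, DESeq2 and its size factors, the library total alone, scaling without the hair lists, crossed pairs as a block, edgeR fold changes in the size rule and camera on log2 CPM. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and the checks and figures used Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The edgeR test was checked on simulated counts for 12399 genes with the means, library sizes and dispersions of this comparison and 200 changed genes. It recovered 1 of 67 genes changed 1.5-fold (1.49%), 20 of 67 changed 2-fold (29.9%) and 62 of 66 changed 4-fold (93.9%). It also made 13 false calls, a larger share of its calls than the adjusted p threshold is meant to allow. The edgeR test thus exceeded its stated error rate in that simulation. Camera called a shifted list and 0 of 20 unchanged lists. Genes were simulated independently of each other, with far fewer changed than the 7097 called here, and camera was run on log2 CPM. The check thus does not cover correlation between genes or scaling when many genes change. Of the gene IDs, 17685 matched a RefSeq table of assembly GRCm38.p6, the assembly that mm10 stands for, from which coordinates were taken.

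The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples. Counts of replicate libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 86.7 in wild type and 67.1 in LDB2-/-, so each library was used as 1 replicate. Total counts of 54095522 to 68436842 per library put the limit that a count of 0 allows between 0.0438 and 0.0555 CPM, which covers counting error only.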

Results

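RNA was measured in back skin epidermis of C57BL/6 mice at postnatal day 63, with 2 libraries from wild type and 2 from LDB2-/- animals. Ldb2 encodes an adaptor protein that binds LIM domain transcription factors. The total count was 67307536 and 57517162 in wild type libraries 1 and 2, and 54095522 and 68436842 in LDB2-/- libraries 1 and 2. Counts were found for 16416 and 16599 genes in wild type and for 15671 and 15468 genes in LDB2-/-. Levels below are TMM-scaled CPM, given as mean ± SD with n = 2 per genotype. These are the counts of a gene per 1e+06 counts of its library, whose total over tested genes was multiplied by its TMM factor. Fold changes are of LDB2-/- over wild type, with adjusted p from the edgeR quasi-likelihood test.

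The targeted gene could not check the genotype labels. Ldb2 (gene ID 16826, chromosome 5, 44435955 to 44799759, mm10, protein coding) had 0 and 8 counts in wild type and 0 and 0 in LDB2-/-, so it was near the detection limit in both genotypes and was not tested. A count of 0 in LDB2-/- library 1 still allows up to 0.0555 CPM by the unscaled library total, a limit that covers counting error only. Its paralog Ldb1 (gene ID 16825, chromosome 19, 46031525 to 46048145) was at 225.9 ± 14.9 in wild type and 250.5 ± 4.14 in LDB2-/-. The log2 fold change of Ldb1 was 0.15 (SE 0.11, adjusted p = 0.290). It turned negative when libraries were scaled by their total alone (-0.17) and with limma on FPKM. There quantile normalization called Ldb1 lower (-0.23, adjusted p = 0.0463, the lowest of its alternatives, which went up to 0.672). Lhx2, a LIM homeobox gene of hair follicle progenitors, rose by 1.07 on the log2 scale (SE 0.17, adjusted p = 0.00325), from 30.1 ± 6.22 to 63.3 ± 1.67. Of the sex check genes, Xist was present in all 4 libraries, at 426.1 and 615.9 in wild type and 267.3 and 176.9 in LDB2-/-, and fell by 1.23 on the log2 scale (adjusted p = 0.0102). The Y-linked gene Eif2s3y had 0, 0, 0 and 22 counts in the same order. Ddx3y, Kdm5d and Uty were not among the genes of the deposited table. Xist in every library and so few Y-linked counts argue against male samples in either genotype, so the fall of Xist does not show a sex difference. The 22 Eif2s3y counts in LDB2-/- library 2 stay unexplained.

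The comparison of LDB2-/- with wild type asks how loss of Ldb2 alters the transcriptome of adult skin epidermis. Genes of the growing hair, from its keratins to its pigment cells, were far higher in LDB2-/-, while keratinocyte genes of the basal layer, the suprabasal layers and the sebaceous gland were lower. Krt27, a keratin of the inner root sheath, was at 40.2 ± 31.1 in wild type and 13832 ± 1837 in LDB2-/-. Krt10, the main keratin of suprabasal epidermis, was at 13693 ± 1718 in wild type and 1678 ± 142.7 in LDB2-/-. The hair shaft, inner root sheath and keratin-associated lists together took 0.071% and 0.168% of the counts in wild type and 13.8% and 14.3% in LDB2-/-. The suprabasal and granular lists together took 4.58% and 4.0% in wild type and 1.02% and 0.968% in LDB2-/-. The gene with the most counts was Krt10 in both wild type libraries (1.64% and 1.40%), Tchh, the inner root sheath protein trichohyalin, in LDB2-/- library 1 (3.31%), and Krt71 in LDB2-/- library 2 (3.29%).

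**Figure D1:**
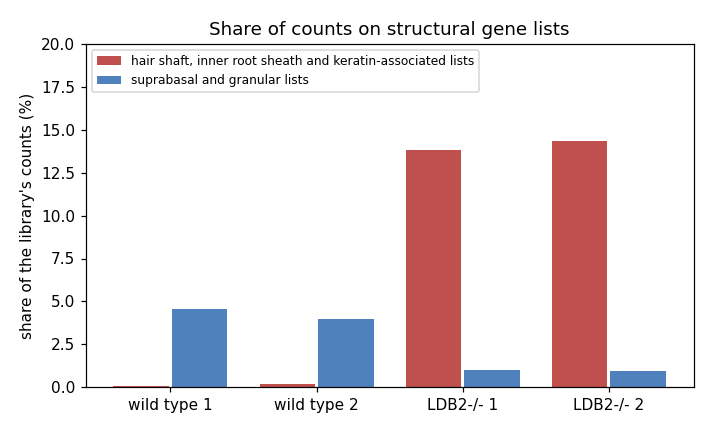
Share of each library's counts, in percent, on the hair shaft, inner root sheath and keratin-associated lists (red) and on the suprabasal and granular lists (blue), with 1 pair of bars per library. The red bars are at 0.071% and 0.168% in wild type and at 13.8% and 14.3% in LDB2-/-.

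Of 12400 genes tested, 7097 were called at an adjusted p under 0.05, 3521 higher and 3576 lower in LDB2-/-. Of these, 1666 were at least 2-fold higher and 2008 at least 2-fold lower, and 341 were at least 16-fold higher against 69 at least 16-fold lower. The balance of directions depended on the scaling: with the library total alone, which moved the median log2 fold change of all tested genes from -0.01 to -0.33, 2248 genes were higher and 5096 lower, and limma on log2(FPKM + 1) gave 2393 higher and 5350 lower. In the authors' deposited table, 8272 genes passed an adjusted p of 0.05, 4090 higher and 4182 lower in LDB2-/-. There 7001 of the 7097 genes called here passed in the same direction and 0 in the other. Both libraries of one genotype lay above both of the other for 83.7% of tested genes, where chance gives 33.3% with no shift between genotypes, and for 82.5% after TMM scaling. The median gene differed by -0.29 in log2(FPKM + 1). A difference of at least 1 on that scale without overlap was found for 3292 genes, 990 higher and 2302 lower. With quantile normalization the same rule gave 1280 higher and 1516 lower. Across genes, the correlation of log2(FPKM + 1) was 0.983 between the wild type libraries and 0.987 between the LDB2-/- libraries, and 0.806 to 0.826 between genotypes, over genes that are not independent replicates.

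The genes with the smallest p among those higher in LDB2-/- were mostly low in wild type and abundant in LDB2-/-. Bambi (gene ID 68010, chromosome 18, 3507011 to 3516404), a decoy receptor of TGF-beta and BMP signalling, rose from 3.22 ± 0.26 to 228.5 ± 10.4, a log2 fold change of 6.15 (SE 0.14, adjusted p = 6.49e-05). Msx2 (gene ID 17702, chromosome 13, 53466881 to 53472780), a homeobox gene of the hair matrix, rose by 6.05 on the log2 scale (SE 0.15, same adjusted p) from 5.66 ± 0.31 to 373.9 ± 31.6. The Wnt pathway regulator Nkd2 (gene ID 72293, chromosome 13, 73818534 to 73847631) rose by 5.25, and Krt75 (gene ID 109052, chromosome 15, 101563343 to 101573904), a keratin of the companion layer, rose by 5.38 from 18.2 ± 0.78 to 759.1 ± 2.94. The phosphatase Dusp2 rose by 5.99, Fhod3 by 4.84, the keratin-associated gene Krtap6-5 by 6.36, the tubulin Tubb6 by 4.99, Pinlyp by 4.23, Stox1 by 8.95, the erythroid haem synthesis enzyme Alas2 by 5.36 and the iron reductase Cybrd1 by 5.80.

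The matching set of lower genes held epidermal differentiation genes and stress-responsive transcription factors. Flg2 (gene ID 229574, chromosome 3, 93197273 to 93221377), a filaggrin family protein of the cornified layer, fell by 5.24 on the log2 scale (SE 0.19, adjusted p = 7.68e-05), from 228.2 ± 38.8 to 6.03 ± 0.64. Sema3d (gene ID 108151, chromosome 5, 12383161 to 12588953), a secreted semaphorin, fell by 4.22 (SE 0.13), from 88.2 ± 0.41 to 4.74 ± 0.31. The nuclear receptor Rora (gene ID 19883, chromosome 9, 68653404 to 69388246) fell by 3.84, and log2 fold changes were -3.74 for the immediate early gene Atf3, -3.35 for Nr4a1, another such gene, and -3.40 for the matricellular gene Cyr61. They were -3.64 for Kctd12, -3.64 for Clca2, -3.58 for Gdpd2, -3.37 for Ccdc3, -2.99 for Krt78 and -2.94 for the cornified layer gene Kprp.

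**Figure D2:**
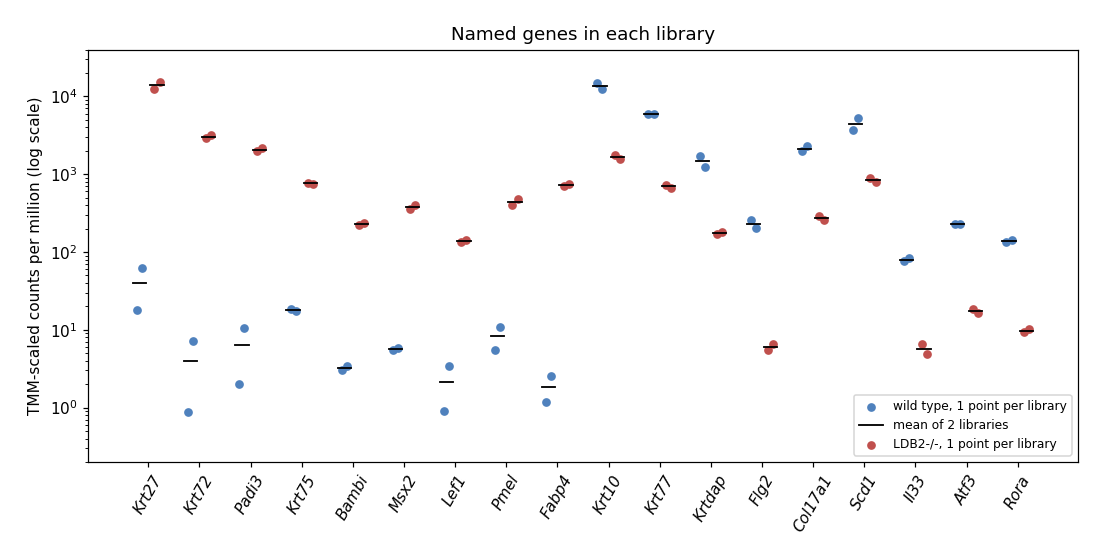
TMM-scaled CPM on a log axis for 18 of the named genes, with 1 point per library (blue wild type, red LDB2-/-) and a black line at the mean of 2 libraries. Krt27 rose from a mean of 40.2 to 13832 and Krt10 fell from 13693 to 1678.

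Hair structural genes rose nearly as a block. Of the 28 members of the hair shaft and inner root sheath list, 27 rose, with a median log2 fold change of 7.25, and only Gata3 did not pass (0.32, adjusted p = 0.068). On log2(FPKM + 1), relative to all genes, the median difference was 7.54, with 6.27 without wild type replicate 1 and 8.71 without wild type replicate 2. Adjusted over the list alone, all 28 passed. Krt72 rose by 9.57 (SE 1.15, adjusted p = 0.00135), from 3.99 ± 4.38 to 3016 ± 197.0. Krt26 rose by 8.55, Krt27 by 8.43 (SE 0.75), and Padi3, which citrullinates trichohyalin, by 8.35. All 48 tested of the 54 keratin-associated genes with deposited values rose, with a median of 6.96. They encode matrix proteins of the hair shaft. The median was 6.92 with Krtap5-4, at 0 in both wild type libraries, set to its lower bound. A gene under 1 FPKM in both wild type libraries was tested only if it reached 1 FPKM in both LDB2-/- libraries. With no filter the median of this list on log2(FPKM + 1), relative to all genes, was 5.01, against 5.48 with it. Krtap12-1 rose by 8.63, Krtap9-1 by 8.30 and Krtap1-3 by 8.15, and Krtap5-4 was higher by at least 6.21 on the log2 scale, against 3 counts over the wild type group. Camera called both lists higher (adjusted p = 9.92e-19 and 6.43e-32), and each had an adjusted p = 0.45 with an estimated correlation. Near-identical keratin-associated genes can share reads, so single members are less certain than the list. The levels of hair genes differed between the wild type libraries, as the SD of 31.1 on a mean of 40.2 for Krt27 shows.

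Many but not all signalling genes of the growing follicle rose too. In the Wnt and hedgehog list 8 of 12 tested members rose, Wnt3 and Wnt10a fell (-1.09 and -0.92) and Axin2 (-0.10) and Wnt10b (0.32) did not pass. The Wnt effector Lef1 rose by 6.02 (SE 0.61, adjusted p = 0.000766), Nkd1 by 5.37 and the hedgehog ligand Shh by 5.11 (SE 1.24, adjusted p = 0.0156). The list was called higher (camera adjusted p = 0.00613), a call lost with a mean FPKM of 5 or more (adjusted p = 0.192), with fry (adjusted p = 0.0744) and with an estimated correlation (adjusted p = 0.581), and 0.00103 was the lowest of its alternatives. Shh had 0 and 71 counts in wild type, and its call was lost in 2 of 19 alternatives, with adjusted p from 2.86e-06 to 0.141. In the BMP and TGF-beta list 10 of 17 rose, among them the inhibitory Smad6 (3.68) and the BMP target Id3 (2.76), while Fst (-2.22), Tgfb2 (-1.07) and Tgfb3 (-1.19) were among 4 that fell, and Id2 (-0.17), Id4 (-0.01) and Grem1 (-2.93, adjusted p = 0.084) did not pass. Grem1, with 36 and 0 counts in LDB2-/-, was called lower without LDB2-/- replicate 1 (adjusted p = 0.000195) and without replicate 2 (adjusted p = 0.0156), and its adjusted p ran up to 0.349 over all alternatives. This list, with a median of 0.94, or 0.62 with the library total alone, was called higher too (adjusted p = 0.0121, and adjusted p = 0.526 with an estimated correlation). Of 15 listed dermal papilla genes only 3 were tested, too few for a list test. All 3 rose, Wnt5a by 3.05, the Wnt inhibitor Notum by 2.82 and Crabp1 by 1.86. Crabp1 was no longer called without wild type replicate 2 (1.41, adjusted p = 0.122, the highest of its alternatives, which went down to 0.00809).

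All 12 melanocyte genes rose, with a median of 5.39 (camera adjusted p = 7.32e-10, and adjusted p = 0.45 with an estimated correlation). Mlana rose by 6.98, the channel gene Trpm1 by 6.01, the transporter gene Slc45a2 by 5.80, and the melanosome matrix gene Pmel by 5.74 (SE 0.38), from 8.25 ± 3.80 to 439.3 ± 58.7.

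Genes of the basal layer fell. Of 14 members of the basal keratinocyte list 13 fell and only Cdh3, the P-cadherin gene, rose (0.92), with a list median of -1.56 (camera adjusted p = 0.000442, and adjusted p = 0.461 with an estimated correlation). The hemidesmosome collagen Col17a1 (chromosome 19, 47646341 to 47692042) fell by 2.95 (SE 0.17, adjusted p = 0.000164), from 2129 ± 201.1 to 274.8 ± 23.7. The integrin Itga6 (-2.38), the laminin chain Lamb3 (-2.31) and the cytolinker Dst (-2.12) fell too. Of 11 suprabasal members 8 fell, Mt4 rose by 2.53, and Dsc1 (0.29) and Lgals7 (-0.11) did not pass. Krtdap (-3.09), Krt77 (-3.08) and Krt10 (-3.03, SE 0.22, adjusted p = 0.000276) fell most. The suprabasal call (adjusted p = 0.0234, and adjusted p = 0.581 with an estimated correlation) was lost without LDB2-/- replicate 2 (adjusted p = 0.0655, in a range over the alternatives from 0.00045 to 0.581).

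The granular and cornified list was mixed, with 21 of 33 tested members lower and 8 higher, or 22 lower and 8 higher adjusted over the list alone, and a median of -1.34 (camera adjusted p = 0.0186, and adjusted p = 0.45 with an estimated correlation). Flg2 and Hrnr, both of the filaggrin family, had log2 fold changes of -5.24 and -5.21. Lce3c rose by 4.84, and Lce3a, at 0 in both wild type libraries, was higher by at least 5.35. Casp14 (-0.50), Rptn (0.28), Cdsn (0.35) and Asprv1 (-0.17) did not pass. The late cornified envelope genes are close copies of each other and can share reads. In the barrier lipid list 8 of 16 fell, 4 rose (Cers3, Cyp4f39, Pnpla1 and Smpd1) and 4 did not pass, among them Ugcg, Sptlc2 and Nipal4, and the list, with a median of -0.35, or -0.67 with the library total alone, was not called by camera (adjusted p = 0.191) but was by fry (adjusted p = 0.0111). Alox12b, a lipoxygenase of the skin barrier, fell by 3.23, followed by Elovl4 (-2.33), Aloxe3 (-2.29) and Fa2h (-2.19). In the stressed keratinocyte list 10 of 19 rose, the beta-defensin Defb14 (-1.55), Il1f6 (-4.12) and Il1f9 (-3.53) fell, and the list was called higher (adjusted p = 0.0255, and adjusted p = 0.45 with an estimated correlation). Its leading members were the envelope genes Sprr2h (4.43) and Sprr1a (3.80). That call was lost with quantile normalization (adjusted p = 0.166), and it was lost in 6 of 16 alternatives, whose adjusted p ran from 0.00217 to 0.45.

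All 14 sebaceous gland genes fell, with a median of -2.06 (camera adjusted p = 3.45e-06, and adjusted p = 0.45 with an estimated correlation). The melanocortin receptor Mc5r fell by 5.38, and the desaturase Scd1 fell by 2.42 (SE 0.24, adjusted p = 0.000707), from 4473 ± 1126 to 835.8 ± 69.4, with Far2 at -2.32 and Dgat2l6 at -2.23. Of 8 upper follicle genes 7 fell, with Cst6 not passing (-0.31), and the list was called lower (adjusted p = 0.0036, and adjusted p = 0.45 with an estimated correlation). The largest falls were in Lgr6 (-2.72), Gata6 (-1.94), Defb6 (-1.70) and Sostdc1 (-1.61). The bulge list split, with 6 of 16 members higher and 6 lower, and was not called (adjusted p = 0.675). Nfatc1 (-2.99), Postn (-2.74) and Krt24 (-2.73) fell, and Bmp6 rose by 2.70. Cd34 (0.41), Sox9 (-0.02), Lgr5 (0.31) and Dkk3 (-0.19) did not pass. The bulge median was 0.14 and its mean -0.08, and the median was -0.17 with the library total alone. On log2(FPKM + 1), relative to all genes, the bulge median was 0.157. It was 0.344 without wild type replicate 1 and -0.136 without wild type replicate 2.

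Skeletal muscle, endothelial, fibroblast and red cell lists were called higher by camera with the preset correlation and not with an estimated one (adjusted p = 0.45 for each), while the Schwann cell and adipocyte lists were mixed. Of 10 tested skeletal muscle genes 9 rose, with a median of 4.76, and only Eno3 did not pass (0.42). A gene under 1 FPKM in both wild type libraries could be tested only if it reached 1 FPKM in both LDB2-/- libraries. Rises among such genes, in every list, are therefore partly fixed by the filter. Among such genes were Crabp1, Pf4, F13a1, Retnlg, Cox4i2, Cox7a1, Gfra3, Mal, S100b, Prx, Krtap5-4 and Krtap12-1. The tests covered 10 of 19 muscle, 6 of 16 endothelial, 14 of 20 fibroblast and 3 of 9 mast cell genes with deposited values. With no filter the muscle, endothelial and fibroblast medians were 3.96, 2.72 and 1.43. Acta1 rose by 6.21, from 0.28 ± 0.09 to 20.7 ± 2.66, Tnnt3 by 5.89, Myl1 by 5.11 and Atp2a1 by 5.08, while Ttn, a gene too low to test, had 4 and 14 counts in wild type and 0 and 0 in LDB2-/-. All 6 tested endothelial genes rose, with a median of 3.19, led by Cldn5 (5.52), Eng (4.12), Egfl7 (3.26) and Plvap (3.13). Of 14 fibroblast and matrix genes 13 rose, with a median of 1.48, and Col6a1 did not pass (-0.32). Dcn rose by 3.47, Eln by 2.99, Mfap5 by 1.96 and Fap by 1.85. Mfap5 was not called without wild type replicate 2 (adjusted p = 0.0785) or without LDB2-/- replicate 2 (adjusted p = 0.0678), and the adjusted p of its alternatives went down to 0.00267. Of 5 tested red cell genes 4 rose, among them Hba-a2 by 5.78, Hbb-bt by 7.46 and Hba-a1 by 3.87, with Hbb-bs not passing (2.38). Read sharing between the similar globin copies was not tested, and Hba-a1 was not called with the robust fit (adjusted p = 0.122, from 8.13e-05 over its alternatives). In wild type 1 and 2, Hbb-bs had 6091 and 0 counts, and the similar gene Hbb-b1 had 6 and 6824. The Hbb genes together had 8464 and 9344 counts there, and 241011 and 350867 in LDB2-/- 1 and 2. Hbb-bs alone thus does not describe the Hbb genes. The preset correlation gave adjusted p = 1.78e-06, 7.01e-05, 2.5e-05 and 0.000238 for the muscle, endothelial, fibroblast and red cell lists. The red cell median relative to all genes on log2(FPKM + 1) was 4.20, and it was 5.02 and 2.93 without wild type replicate 1 and 2, and 4.85 and 3.36 without LDB2-/- replicate 1 and 2. Among 4 smooth muscle genes Tagln (5.91), Acta2 (4.43) and Smtn (1.73) rose and Mylk (-0.39) did not pass, except with the library total alone (adjusted p = 0.029, up to 0.498 over its alternatives), and the 3 tested mast cell genes Cma1 (4.26), Mcpt4 (3.20) and Tpsb2 (2.79) rose. These mast cell genes were all under 1 FPKM in both wild type libraries, so they passed the filter through LDB2-/- only. In the Schwann cell list Gfra3 (5.82), Mal (4.17), S100b (2.78) and Prx (2.07) rose, Mbp (-1.83) and Pmp22 (-0.85) fell and Ngfr (-0.57) did not pass, with no call for the list (adjusted p = 0.191) but one with no expression filter (adjusted p = 0.0225, in a range over the alternatives from 0.00131 to 0.675). In the adipocyte list Fabp4 rose by 8.60 and Lipe by 2.88, Cidec (-2.88), Pparg (-2.15), Lpl (-1.82) and Slc2a4 (-1.19) fell, and Pnpla2 did not pass (0.09). That list was not called (adjusted p = 0.864), with a median of -1.19 and a mean of 0.51. Its members Adipoq, Plin1 and Cfd were too low to test, at 7 counts or fewer in every library.

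Immune genes moved in both directions. Of 12 T cell genes 9 fell and Cd2 (-0.77), Lck (-0.60) and Cxcr6 (-0.77) did not pass over all genes, while all 12 passed adjusted over the list alone, with a median of -1.12 (camera adjusted p = 0.00172, and adjusted p = 0.563 with an estimated correlation). Il2rb (-1.71), Thy1 (-1.64), Cd3g (-1.58) and Zap70 (-1.53) fell most. Of 10 Langerhans and dendritic genes 7 fell, or 8 adjusted over the list alone, Mfge8 rose by 1.26, and Cd74 (-0.45) and Ccl22 (-0.72) did not pass. Cd207, the langerin gene, fell by 1.64, Cd86 (-1.44) and Ltc4s (-0.87) fell too, and Ltc4s was not called without wild type replicate 1 (adjusted p = 0.0746), wild type replicate 2 (adjusted p = 0.0837) or LDB2-/- replicate 1 (adjusted p = 0.0921), with 0.000939 the lowest adjusted p of its alternatives. That list's call (adjusted p = 0.0421, and adjusted p = 0.581 with an estimated correlation) was lost with a mean FPKM of 5 or more (adjusted p = 0.0978) and without LDB2-/- replicate 1 (adjusted p = 0.102, in a range over the alternatives from 0.00658 to 0.581). Of 10 macrophage genes 8 rose, led by Pf4 (3.99), C1qc (2.88), C1qb (2.81) and F13a1 (1.79), while Adgre1 (-0.96) and Csf1r (-0.95) fell. The list was called higher (camera adjusted p = 0.00285, and adjusted p = 0.45 with an estimated correlation). Pf4 and F13a1 were under 1 FPKM in both wild type libraries, so they passed the filter through LDB2-/- only. On log2(FPKM + 1), relative to all genes, the macrophage median was 1.24, and 0.957 with no filter (camera adjusted p = 0.000906). Of 12 cytokine and chemokine genes 10 fell, Il1b rose by 0.96 and Ccl5 (1.33) did not pass (camera adjusted p = 0.0213, and adjusted p = 0.45 with an estimated correlation). The alarmin Il33 fell by 3.80 (SE 0.19, adjusted p = 0.000123), Cxcl1 (-4.59) and Ccl2 (-2.58) fell too, and Ccl20, at 0 in both LDB2-/- libraries, had a log2 fold change of -6.56 or lower. In the interferon list Cxcl10 (-1.53) and Usp18 (-1.29) were among 3 that fell, 9 of 12 did not pass, among them Rtp4 (-2.29) and Oasl2 (-1.53), and the list was not called (adjusted p = 0.248), though it was without wild type replicate 1 (adjusted p = 0.0143, in a range over the alternatives from 0.0045 to 0.735). Usp18 was not called without wild type replicate 2 (adjusted p = 0.0647, from 0.00116 over its alternatives). Rtp4 and Oasl2 were called without wild type replicate 1 (adjusted p = 0.0168 and 0.00186) and without LDB2-/- replicate 1 (adjusted p = 0.00338 and 0.0398), and their adjusted p ran up to 0.32 and 0.734 over their alternatives. Of 4 neutrophil genes Il1r2 (-1.94) and Mmp9 (-1.48) fell, and Retnlg, at 0 in wild type, was higher by at least 6.10. Cxcr2 (-0.58) did not pass. Its adjusted p ran from 0.0309 to 0.497 over all its alternatives, so some but not all of them called it lower.

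Regulatory and metabolic lists were also compared. Of 14 circadian clock genes 12 fell, Cry1 rose by 0.96 and Bhlhe41 (-0.60) did not pass, with a median of -1.45 (camera adjusted p = 0.00232, and adjusted p = 0.45 with an estimated correlation). The largest falls were in Npas2 (-3.05), Hlf (-2.81), Nr1d2 (-2.62) and Clock (-2.61). Of 18 immediate early and heat shock genes 13 fell, Jund (0.92) and Hsph1 (0.35) rose and Junb (0.15), Ier2 (-0.20) and Ier3 (-0.06) did not pass (camera adjusted p = 0.000515, and adjusted p = 0.45 with an estimated correlation). Besides Atf3 (-3.74) and Nr4a1 (-3.35), Fosb (-3.19) and Dusp1 (-2.94) fell most. Of 20 sterol and fatty acid synthesis genes 14 fell and 0 rose, with a median of -0.60, or -0.92 with the library total alone (camera adjusted p = 8.68e-05, and adjusted p = 0.553 with an estimated correlation), with Hmgcs1 (-1.38) and Acly (-1.34) among those that fell most. Of 77 cytosolic ribosomal protein genes 58 rose, or 59 adjusted over the list alone, with a median of 0.69, or 0.39 after the trend with gene length was subtracted and 0.37 with the library total alone (camera adjusted p = 1.81e-08, and adjusted p = 0.606 with an estimated correlation), and the call was lost and the direction turned with quantile normalization (adjusted p = 0.602, in a range over the alternatives from 2.68e-10 to 0.606), and fry (adjusted p = 0.138) and its mixed test (adjusted p = 0.0542) did not call the list. Rps4l, annotated as a transcribed pseudogene, rose by 1.75, Rpl26 by 1.65 and Rpl38 by 1.2, and Rps27 (1.43) did not pass. Rpl26 was low, with 48 and 22 counts in wild type and 95 and 73 in LDB2-/-. Rpl38 had 12274 to 32067 counts over the libraries. Rps27 had 203 counts in wild type library 2 against 43722 in library 1, and without wild type replicate 1 its log2 fold change was 7.99 (adjusted p = 5.67e-07, up to 0.706 over its alternatives). Rpl26 was not called without wild type replicate 2 (adjusted p = 0.167) or LDB2-/- replicate 1 (adjusted p = 0.0623), with 0.00832 its lowest. Of 84 respiratory chain genes 40 rose, or 31 adjusted over the list alone, Ndufa4l2 fell by 1.86, and the median was 0.43, or 0.16 after the length trend and 0.11 with the library total alone (camera adjusted p = 0.000515, and adjusted p = 0.71 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.376) and with fry (adjusted p = 0.436), in a range over the alternatives from 2.84e-06 to 0.71. Cox4i2 rose by 6.92, Cox7a1 by 2.72 and Ndufb7 by 1.3. Cox7a1 was not called without wild type replicate 2 (adjusted p = 0.0528, from 0.00179 over its alternatives).

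Cell cycle genes showed small differences, with a median of 0.36, or 0.048 with the library total alone, 11 of 27 higher, Mcm4 lower (-0.51) and no call for the list (adjusted p = 0.116). Ube2c rose by 0.89, Plk1 by 0.73, Mcm5 by 0.67 and Aurkb by 0.66. The list was called higher with quantile normalization (adjusted p = 0.0139), with upper quartile scaling (adjusted p = 0.0364), on log2 CPM (adjusted p = 0.0113) and without wild type replicate 2 (adjusted p = 0.0461, in a range over the alternatives from 0.00755 to 0.817). Mcm5 was not called without LDB2-/- replicate 2 (adjusted p = 0.0587, from 0.00165 to 0.157 over its alternatives). In the Notch list Heyl (5.43) and Hes1 (1.06) rose, Dll1 (-1.91) and Jag2 (-1.35) fell and Notch1 (0.21), Notch2 (0.56), Notch3 (-0.06), Jag1 (-0.17) and Nrarp (-0.13) did not pass. The Notch median was -0.06, or 0.39 after the length trend was subtracted and -0.38 with the library total alone, its mean was 0.40 and its test pointed higher with no call (adjusted p = 0.864). In the LIM domain and LDB complex list Lhx2 (1.07) and Ssbp4 (0.89) rose, Lmo1 (-1.47), Ssbp2 (-1.06) and Ssbp3 (-0.30) fell and Ldb1 (0.15), Lmo2 (0.35), Lmo4 (0.02) and Rlim (0.21) did not pass. Its median was 0.15, or -0.17 with the library total alone, its mean was -0.02 and its test pointed lower with no call (adjusted p = 0.849).

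**Figure D3:**
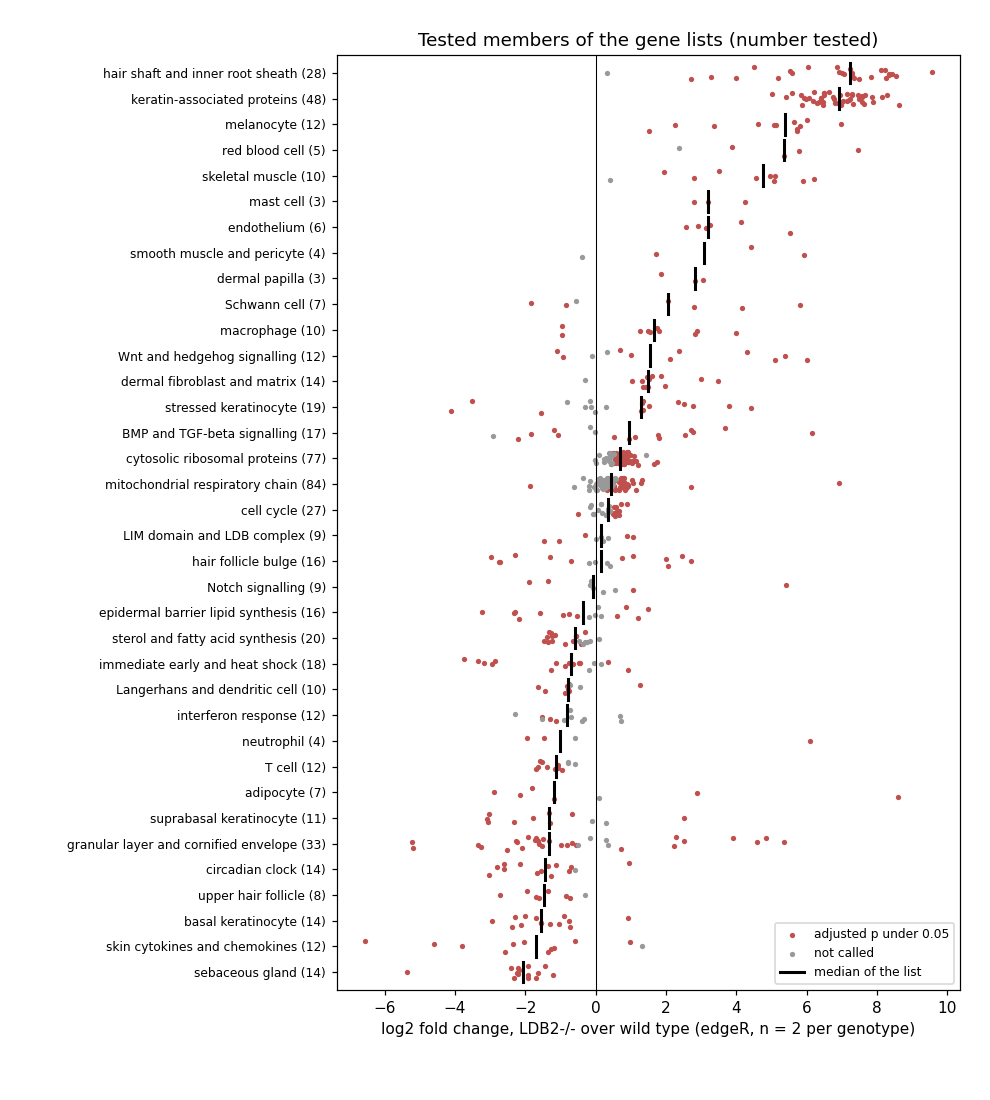
Log2 fold change of LDB2-/- over wild type for each tested member of the 36 gene lists (rows, with the number tested), red where the edgeR adjusted p was under 0.05 and grey where not, with a black line at the list's median. Genes at 0 in 1 genotype are drawn at their bound, and list medians run from -2.06 for the sebaceous gland list to 7.25 for the hair shaft and inner root sheath list.

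Camera with a preset correlation called 24 of 32 lists, 13 higher and 11 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.45 and 1 list had an unadjusted p under 0.05 (0.0474). Fry, which asks whether a list's genes move on balance in one direction, called 24 lists, 9 higher and 15 lower, and its mixed test, for change in either direction, called 31. Fry tests each list against no change on log2(FPKM + 1), where the median gene differed by -0.29. That shift favours lower calls, so fry is not an independent check of the directions that camera gave. Adjusted over the list alone, the counts of higher and lower genes were those given above for each list where no other count is stated. With 2 libraries per genotype the smallest p of a two-sided exact permutation test is 0.333, so p-values here rest on the spread that edgeR and limma pool across genes.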

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

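The added alternatives (limma on the authors' normalized values, DESeq2 and its size factors, the library total alone, scaling without the hair lists, crossed pairs, edgeR folds for the size rule, and camera on log2 CPM) were chosen after the data were seen. The 7097 calls became 5101 with a mean FPKM of 5 or more, where fewer genes were tested, and up to 7825 with limma at a pseudocount of 5, and stayed within 1.5-fold under every setting run. Leaving out each library in turn gave 5669 to 6702 calls, 2998 to 3646 genes past the size rule and 23 to 25 lists, with the lone library of a genotype assumed to vary like the others. With the replicate number as a replicate block, 6092 genes and 24 lists were called, and the correlation across genes of the difference between replicates 1 and 2 in the genotypes was -0.154, so the numbers do not pair the samples. Crossed pairs gave 7269 calls. Genes past the size rule fell from 3292 to 1554 with a pseudocount of 5, which shrinks differences of low genes, and to 2129 with a mean FPKM of 5 or more, where fewer genes were tested. The 24 list calls became 0 with an estimated correlation (-0.165 to 0.908). Over lists and alternatives, 439 list tests kept direction and side of the threshold, 18 gained a call, 38 lost one and 12 turned, and for named genes these numbers were 3153, 25, 31 and 5.

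Values of lists are medians relative to all genes. The adipocyte test turned higher with no filter (0.0935), a mean FPKM of 5 or more (-0.0129), the replicate block (-0.495) and without wild type replicate 1 or 2 or LDB2-/- replicate 1, where leaving out each library gave -0.511 to -0.48. The LIM test turned higher with no filter (0.0875) and on log2 CPM (0.168), where the bulge test turned lower (0.223), and the Notch test turned lower with quantile normalization (-0.062) and without wild type replicate 1 (-0.13 to 0.0924 over the libraries left out). Camera called none of these 4 lists here or under its alternatives. Fry called adipocyte, LIM and bulge genes, but it makes no allowance for the shift of the median gene by -0.29 in log2(FPKM + 1). The ribosomal test turned lower with quantile normalization (0.00576). Ldb1 was lower with limma on log2(FPKM + 1) (-0.141, with pseudocounts of 0.1 and 5 -0.142 and -0.136), quantile normalization (-0.226) and the library total alone (-0.168). With limma on log2(FPKM + 1) and with the library total alone the median gene was at -0.287 and -0.331, lower than Ldb1. Quantile normalization put the median gene at -0.0469, above Ldb1. The turn of Ldb1 in the former settings thus follows a shift of all genes, and the cause of the other changes was not tested. Of 163 named genes 142 kept their direction and their side of the threshold under every setting run. Calls of Krtap1-3 (adjusted p up to 0.0608), Pf4 (0.0691), Aurkb (0.0766) and Cxcl1 (0.0867) were lost in 1, 1, 4 and 2 alternatives. Ldb2 has no value because it did not pass the filter, and no symbol repeated, so the choice between rows of 1 symbol was not run. Depth limits genes near the limit of 0.0438 to 0.0555 CPM, Ldb2 among them.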

Other observations

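The 12 gene families tested for the first paragraph were chosen after their values were seen, and the tests below were too, except the length tests on hair and on keratinocyte genes. Families were defined by gene name. All 11 tested Skint genes, immunoglobulin family genes of keratinocytes and thymus, fell, with a median log2 fold change of -3.23 (two-sided Fisher's exact test against other tested genes, adjusted p = 3.89e-06 over 24 tests). Of 27 tested H2 genes, which encode histocompatibility antigens, 25 fell and 0 rose, with a median of -1.65 (adjusted p = 6.57e-11), 3 of them also on the Langerhans list. Of 16 Serpinb protease inhibitor genes 13 fell (median -1.48, adjusted p = 5.53e-05), and of 30 cytochrome P450 genes, 2 of them on a list, 19 fell (median -1.41, adjusted p = 0.0003). Of 12 S100a genes, 3 of them on a list, 9 rose (median 1.58, adjusted p = 0.00201). Of 78 mitochondrial ribosomal protein genes 49 rose and 0 fell, with a median of 0.55 that was 0.26 after subtracting the trend with length and 0.24 with the library total alone (adjusted p = 2.28e-09), and of 47 proteasome genes 30 rose and 4 fell (median 0.52, or 0.33 after length, 0.20 with the library total alone and 0.23 with quantile normalization, adjusted p = 2.37e-06). Of 259 Zfp zinc finger genes 109 fell and 30 rose (median -0.45, or -0.26 after length, adjusted p = 1.26e-05 for the falls). Of 45 keratins, 32 of them on a list, 33 rose (adjusted p = 2.43e-09), as did 5 of 6 Tubb tubulins (adjusted p = 0.0145) and all 3 Padi genes, 1 of them on the hair list (adjusted p = 0.0366). Hox genes split, with 6 of 22 higher and 9 lower (adjusted p = 1.0 and 0.302). Genes of a family are not independent, so these p-values are too small. Each family's median kept its sign with the library total alone and with quantile normalization.

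Short genes tended to be higher and long genes lower in LDB2-/-, with a median log2 fold change of 0.37 in the shortest of 5 equal groups of tested genes and -0.37 in the longest, with length taken as counts over FPKM. Among counts from 10 to 59, even numbers made up 54% and 52.9% in wild type and 57.9% and 60.7% in LDB2-/- (exact binomial 95% intervals for the latter 55.8 to 60.1% and 58.5 to 62.9%), where independent reads would give about equal shares of even and odd. The number of deposited genes at 0 was 1305 and 1122 in wild type and 2050 and 2253 in LDB2-/-. Rps27 had 43722, 203, 35323 and 52902 counts in wild type 1 and 2 and LDB2-/- 1 and 2. The 6 globin genes of the table took 0.022% and 0.027% of counts in wild type and 0.812% and 0.97% in LDB2-/-.

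The 76 tested hair shaft, inner root sheath and keratin-associated genes had a median log2 fold change of 7.00. A few genes taking many counts do not account for it, since the median was 6.90 with library totals that left these genes out. Gene length does not either, with a median of 6.73 after its trend was subtracted. The 8 hair shaft and inner root sheath members that are not keratins had a median of 5.82. Reads shared between similar keratins do not account for the rise of those members. Sharing among the keratins and among the 48 keratin-associated genes was not tested directly. What also stays open is whether hair cycle stage differed between the samples for a reason other than genotype, which cannot be told apart from genotype with 2 libraries each (smallest exact permutation p 0.333). A different hair cycle stage in LDB2-/- skin is thus a hypothesis, and its link to the loss of Ldb2 is untested.

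The 25 basal and suprabasal keratinocyte genes had a median log2 fold change of -1.56. It was -1.66 with library totals that left the hair lists out, so counts taken by hair genes do not account for it, and -1.19 after the length trend was subtracted. A smaller share of interfollicular epidermis in the LDB2-/- samples may account for part of it, but the members' fold changes had an SD of 1.32 and which of them follicle cells also express was not measured, so a smaller share and lower expression per cell cannot be told apart.

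Skeletal muscle, endothelial and fibroblast markers, 30 tested genes of which 0 are on another list and 19 reached 1 CPM in wild type, had a median log2 fold change of 2.67, and with no expression filter the list medians were 3.96, 2.72 and 1.43. The length trend does not account for it, with a median of 2.57 after it was subtracted. A lower share of keratinocyte RNA alone would raise the markers of other cell types alike. The unfiltered fibroblast and T cell medians (1.43 and -1.08) differed by 2.52, against SDs of 0.864 and 0.637. The muscle members, with an SD of 3.41, spread too widely to tell. The T cell list was chosen for this after its fall was seen, and T cells resident in the epidermis would fall with it. The comparison thus cannot decide against a lower share of epidermal RNA as a whole. More deep dermis or muscle in the LDB2-/- samples, with less of the epidermis and its resident T cells, remains a candidate explanation. It cannot be told apart from genotype with 2 libraries each (smallest exact permutation p 0.333). The most abundant tested muscle gene there, Acta1, was at 20.7 ± 2.66 CPM, while Ttn had 0 and 0 counts. The adipocyte genes Adipoq (7 and 0 counts), Plin1 (0 and 0) and Cfd (0 and 7) were also near 0 in LDB2-/- 1 and 2. These 3 genes thus give no sign of fat carried along, though Fabp4 of the same list rose by 8.60. Genotype itself stays open, untested.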
